A study of Mus musculus with 9 samples.

How the data were processed

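RNA from mouse regulatory T cells was measured on 9 Affymetrix expression arrays, 1 per sample. Regulatory T cells restrain other immune cells, and CD4 and CD25 are the surface markers by which they were separated with magnets here, per the labels. The arrays fall into 3 groups of 3: wild type, a conditional Sirt1 knockout made with a CD4 Cre recombinase (CD4-cre), and a conditional Sirt1 knockout made with a Foxp3 Cre recombinase (Foxp3-cre). Sirt1 encodes an NAD-dependent protein deacetylase. Cre removes a marked part of the gene in cells that express the recombinase. Which part of Sirt1 is removed is not given in the sources used here. Groups and replicate numbers were taken from the labels. The series' design text calls the samples of a group independent, but nothing in the labels says that they came from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

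The values are the authors' deposited log2 signals, 1 per probe set and array, and per the submitters' processing notes they were made with RMA, which corrects the background, normalizes between arrays and summarises the probes of a set. The RMA version, the scanner and the genome build are not given in the sources used here, so no coordinates are printed. RMA compresses small differences of dim probe sets, and its normalization between arrays removes any change that is common to all genes. The values span 1.57 to 14.06, with medians between 5.37 and 5.45 on the 9 arrays, and 0 pairs of arrays hold identical values. The number of arrays, 3 per group, limits the precision. The median standard error of a log2 change between 2 groups was 0.11.

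The table holds 22690 probe sets, of which 64 are control probe sets and were left out of the tests. By the platform annotation used here, 20380 of the others carry exactly 1 gene symbol, 691 carry several and 1555 are unnamed. Gene symbols were checked through gene IDs against a RefSeq gene table of the assembly GRCm38.p6, where 20351 of the 20380 matched and 0 symbols changed. That table was otherwise used only for which genes neighbour each other. Each of the 12393 genes was represented by the probe set with the highest mean over the 9 arrays, and 4956 genes had more than 1 probe set. Genes with a mean at or above the 40th percentile of all gene means, a log2 signal of 4.979, were tested, which left 7436.

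Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend and not robust) on the log2 values as deposited, in 1 fit over the 3 groups with 6 residual and 3.37 prior degrees of freedom. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over the 7436 genes. Every adjusted p of a gene is limma's. There were 4 contrasts: CD4-cre minus wild type, Foxp3-cre minus wild type, Foxp3-cre minus CD4-cre, and the mean of both knockouts minus wild type. The contrast between the knockouts is also the test of whether their changes against the shared wild type arrays differ. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so none was used. A change is given as a difference of mean log2 signals, with its standard error (SE).

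Gene lists and markers were written before the data were examined, as were the tests, the rule for named genes and the alternatives, except those marked below as chosen later. The 17 lists cover the sirtuin family, protein acetylation and deacetylation enzymes, the regulatory T cell (Treg) signature, conventional and naive T cell genes, T cell activation and homing genes, effector cytokines, targets of FOXO, p53 and NF-kB, glycolysis, oxidative phosphorylation, fatty acid oxidation, the cell cycle, the interferon response, immediate early genes, heat shock and chaperones, and cytosolic ribosomal proteins. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated per list and with limma's fry. Lists with fewer than 5 tested genes, here the sirtuin family alone, have no test, which left 16. Markers of T cells, CD8 T cells, B cells, plasma cells, NK and innate lymphoid cells, monocytes and macrophages, dendritic cells, neutrophils, mast cells and basophils, erythroid cells, platelets, thymocytes, and stroma and endothelium, with sex-linked genes, were read as a check of what the separation let through.

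Named genes follow a rule. For each knockout against wild type it takes the 10 largest rises and the 10 largest falls among changed genes whose 3 knockout arrays all lie beyond all 3 wild type arrays. For the other contrasts it takes 5 and 5, filled up with the genes of smallest p where fewer pass. It adds Sirt1, Foxp3, Il2ra, Cd4, Ctla4 and Tnfrsf18 always, and from each list up to 4 changed members, or the 2 with the largest change where none passed. Marker genes are named from the marker lists, and genes outside these rules are said to be chosen after their values were seen.

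The same code was tested on simulated arrays that kept each gene's mean and residual spread, in which 200 of the 7436 genes carried known changes in the Foxp3-cre minus wild type contrast, with a further 25 genes shifted together by 0.5. It called 64.2% of the 200 genes' changes of 0.5, 94.0% of those of 1 and 98.5% of those of 2. It made 195 calls there, 10 of them of genes without a planted change, and 0 calls in the CD4-cre contrast, where nothing was planted. Alternatives covered the filter on dim genes, the choice of probe set, the normalization, the variance model, array weights, the arrays in the fit, the replicate number as a block, each array left out in turn and a looser threshold of 0.10. Added after the data were seen were fits with the mean neutrophil marker level or the beta-actin 5' minus 3' control signal as a covariate. Overlap and correlation between the knockouts were set beside 100 simulated pairs of unchanged groups. Each pair shared 3 simulated wild type arrays, which kept each gene's spread and were drawn independently for each gene. Figures were drawn with matplotlib 3.10.9.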

Results

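Regulatory T cells separated by CD4 and CD25 were profiled from wild type mice and from 2 kinds of conditional Sirt1 knockout, 3 arrays each, on the C57BL6 strain background named in the labels. The series title puts the question as how targeting Sirt1 affects the function of these cells. The CD4 Cre acts in T cells in general, while the Foxp3 Cre is driven by the gene of the transcription factor that marks regulatory T cells. Signals are log2 values, so a difference of 1 is a 2-fold change.

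Wild type replicate 2 stood apart from the other 8 arrays. Its correlation with them over all probe sets lay between 0.982 and 0.987, whereas the other arrays correlated at 0.992 or more with each other. RNA quality controls differed as well: the 5' minus 3' signal was -1.53 for beta-actin on that array against -0.68 to -0.45 on the others, and -1.10 against -0.36 to -0.05 for Gapdh. Its signal of the BioB spike-in control was 9.98, against 7.94 to 8.72. The counts below are therefore also given without this array.

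Sirt1 itself is represented by 1 probe set, and it did not separate the knockouts from wild type. Its log2 signals were 7.91, 6.77 and 7.90 in wild type, 7.69, 7.59 and 7.59 in CD4-cre, and 7.66, 7.54 and 7.47 in Foxp3-cre. The change was 0.10 (SE 0.26, limma adjusted p = 0.882) in CD4-cre and 0.03 (SE 0.26, adjusted p = 0.958) in Foxp3-cre. Without wild type replicate 2, the lowest of the 9 values, Sirt1 lay at -0.35 in Foxp3-cre (adjusted p = 0.0301) and -0.28 in CD4-cre (adjusted p = 0.0730). The deleted part is not given in the sources used here, so a probe set outside it would check nothing, and the genotypes below are those of the labels. Of the other sirtuins 3 were tested, and 0 passed in limma over all genes tested. Adjusted over the list alone, Sirt2 rose in CD4-cre, by 0.25, and stood at 0.15 in Foxp3-cre. Sirt3 stood at 0.17 and 0.13, and Sirt7 at -0.03 and -0.18. The list had a median of 0.13 in CD4-cre and 0.08 in Foxp3-cre.

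Foxp3, the lineage factor of regulatory T cells (1 probe set), had log2 signals of 9.39 ± 0.26 in wild type and 9.66 ± 0.04 in CD4-cre (SD, n = 3 arrays). In the Foxp3-cre arrays it read 2.67, 3.38 and 2.83. These values lie at or above only 11.3 to 23.9% of the probe sets of their array, in the range of undetected genes, so the fold is set by the floor of the array. The difference was -6.44 (SE 0.18, limma adjusted p = 2.16e-07) against wild type and -6.70 (SE 0.18, adjusted p = 1.48e-07) against CD4-cre. The other 28 tested members of the Treg signature did not move with it as a set. Between the knockouts their median difference was 0.01, with quartiles of -0.09 and 0.13, and 0 of them passed. Adjusted over the list alone, with Foxp3 in it, 2 members fell. The lowest of the other 28 was Gpr83, at -0.41. Against wild type, Il2ra (the CD25 antigen) stood at -0.01 in CD4-cre and 0.12 in Foxp3-cre. Ctla4, an inhibitory receptor, stood at 0.21 and 0.15, Tnfrsf18, also called GITR, at 0.17 and -0.03, and Cd4 at -0.31 and -0.09. None of these passed the threshold. The cells were separated by CD4 and CD25, so level signals of Cd4 and Il2ra may follow from the separation.

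**Figure D1:**
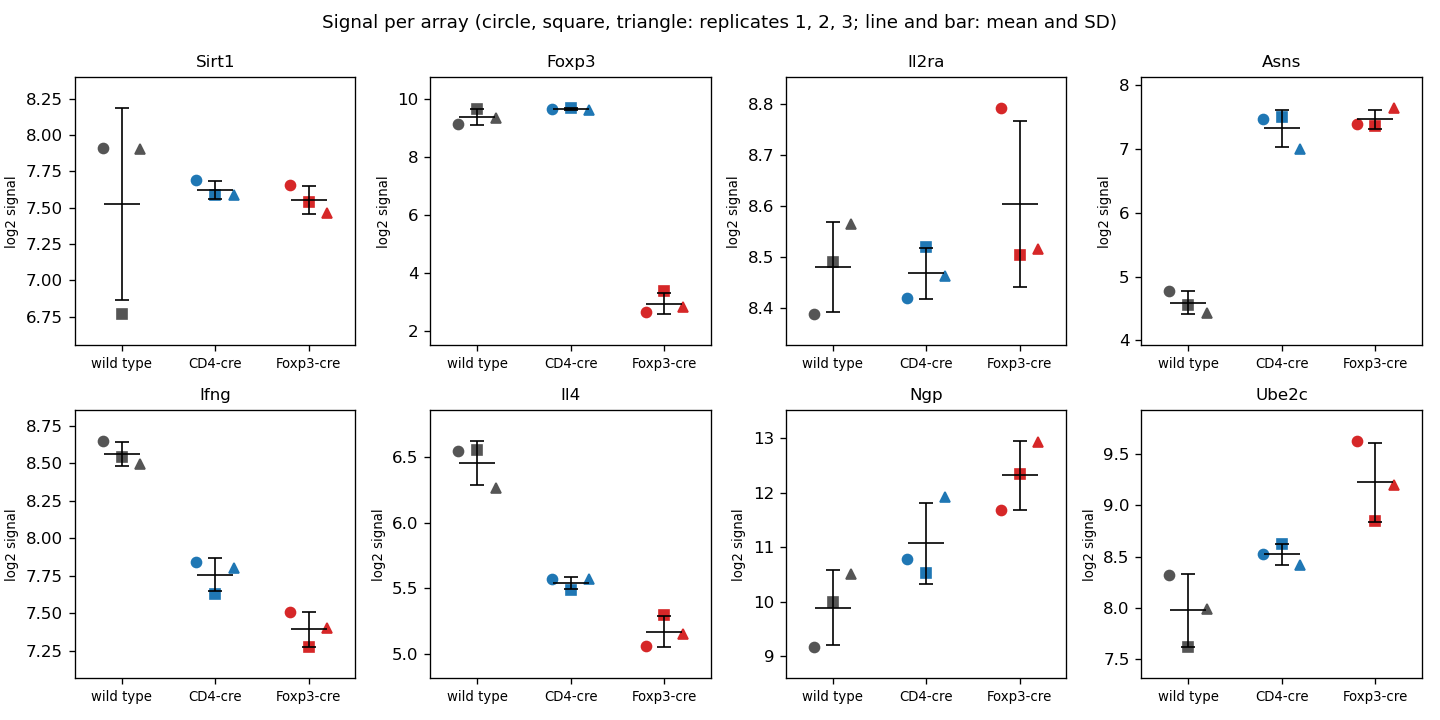
Log2 signal (vertical axes) of 8 genes on each of the 9 arrays, by group, with the mean and SD of 3 arrays per group. Foxp3 lies between 2.67 and 3.38 in Foxp3-cre and above 9 elsewhere, Asns is higher in both knockouts, and Sirt1 of wild type replicate 2 is the lowest at 6.77.

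The comparison of CD4-cre with wild type asks which transcripts differ when Sirt1 is targeted in T cells at large. The largest rise was that of Asns, asparagine synthetase, from 4.59 ± 0.18 to 7.32 ± 0.28 (SD, n = 3 arrays), a change of 2.73 (SE 0.15) or 6.64-fold (limma adjusted p = 0.000113). Sytl1, a synaptotagmin-like protein of vesicle traffic, rose by 1.18 (SE 0.10), Cap1, an actin-binding protein, by 1.13 (SE 0.12), and Kif1b, a kinesin motor, by 0.94 (SE 0.10). Among the falls, the unconventional myosin Myo6 stood at -1.61 (SE 0.21), the glypican Gpc1 at -1.29 (SE 0.19) and Sfn, the 14-3-3 protein sigma, at -1.29 (SE 0.17). Gimap7, a lymphocyte GTPase, fell by 1.09, the water and glycerol channel Aqp9 fell to a 2-fold lower signal, and Pink1, a kinase of mitochondrial quality control, by 0.82. The other genes of the rule rose by 0.72 to 0.88 (Map6, Hyi, Wdtc1, Rab4a, Cox18 and the pseudogene Pisd-ps3) or fell by 0.97 for the lysosomal peptide transporter Abcb9 and by 1.15 for Tmem267.

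By gene group, of 7 tested effector cytokines 2 fell, Il4 by 0.91 (SE 0.10) and Ifng by 0.80 (SE 0.09). The count adjusted over the list alone was also 2, and the list as a whole passed no test (camera adjusted p = 0.102), with a median of 0.04, a mean of -0.16 and a downward direction in the test. NK cell and innate-like T cell genes, a list written after the data were seen, lay lower in 15 of 18 by a median of -0.34, with 0 changed in limma (camera adjusted p = 8.30e-06 over the 3 lists added, adjusted p = 0.118 with an estimated correlation). Interferon response genes shifted down, with 21 of 22 members lower and a median of -0.38 (camera adjusted p = 1.06e-11), but adjusted p = 0.426 with an estimated correlation. Of its members Oasl1, an oligoadenylate synthetase-like protein, fell by 0.89, and 10 fell when adjusted over the list alone. Cell cycle genes shifted up by a median of 0.29, with 28 of 29 members higher but 0 changed, on either adjustment, by limma (camera adjusted p = 0.000280). The estimated correlation gave adjusted p = 0.647, and Aurkb and Ccnb2 had the largest values, 0.58 and 0.61. Conventional and naive T cell genes shifted down by a median of -0.13 (camera adjusted p = 0.00650, adjusted p = 0.606 with an estimated correlation), where 1 of 16, the gut-homing receptor Ccr9, fell by 0.75 and 3 fell adjusted over the list alone. Of 29 Treg signature genes 1 fell, the costimulatory receptor Tnfrsf9 by 0.45, and adjusted over the list alone 3 rose and 1 fell, without a shift of the list (camera adjusted p = 0.339). Of 12 acetylation and deacetylation enzymes 2 rose, the deacetylases Hdac1 and Hdac6, both by 0.44, and also 2 adjusted over the list alone (camera adjusted p = 0.0762). Myb, a transcription factor, was the 1 activation and homing gene of 24 to rise, by 0.57, against 4 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.390), and Rps6 was the 1 ribosomal protein gene of 21 to fall, by 0.70 on either adjustment (camera adjusted p = 0.130). The other lists had 0 changed members by limma over all genes tested and did not shift: the medians were 0.11 for oxidative phosphorylation (camera adjusted p = 0.0606), 0.02 for FOXO targets, 0.01 for p53 targets, 0.01 for NF-kB targets, 0.02 for glycolysis, 0.01 for fatty acid oxidation, 0.01 for immediate early genes and -0.01 for heat shock genes and chaperones (camera adjusted p between 0.158 and 0.946 for these). Adjusted over the list alone, 1 glycolysis gene rose and 2 heat shock genes and chaperones fell.

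In all, 49 of 7436 genes changed in CD4-cre, 17 up and 32 down, 9 of them by over 2-fold. At an unadjusted p under 0.05 there were 1047 genes, against 371.8 by chance. The arrays of both groups were fully separated for 1563 genes, 21.0%, where chance gives 10%. Without wild type replicate 2 the count was 191. It was 30 and 23 without wild type replicates 1 and 3, 11, 4 and 18 without CD4-cre replicates 1, 2 and 3, and 25 and 31 without Foxp3-cre replicates 2 and 3, which share the estimate of the spread, and of the 49 genes Asns, Kif1b, Pink1 and Sytl1 passed in all 9 such fits. Kif1b had 6 other probe sets, 3 above the signal threshold for testing, at 0.64, 0.20 and 0.19, and 3 dim ones, at 0.66, 0.55 and 0.01. Abcb9 had 2 others, at -0.96 and -0.41, and Tnfrsf9 had 2, at -0.07 and, for a dim set, 0.08. Other dim sets stood at -0.40 and -0.01 for Myo6, -0.03 for Aqp9, 0.0009 for Rps6 and -0.55 for Ccr9. The set used for Myo6 had a mean of 5.14, close to the signal threshold of 4.979. With only the wild type and CD4-cre arrays in the fit 22 genes passed, and 1298 with array weights.

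Foxp3-cre against wild type asks the same with Sirt1 targeted in regulatory T cells. Asns again had the largest rise, 2.87 (SE 0.15) or 7.32-fold, to 7.46 ± 0.15 (SD, n = 3 arrays; limma adjusted p = 3.58e-05). Of 7 tested effector cytokines 3 fell, among them Ifng by 1.17 (SE 0.09) and Il4 by 1.29 (SE 0.10). Tbx21, the transcription factor T-bet, fell by 1.16 (SE 0.14), the chemokine receptor Cxcr6 by 1.44 (SE 0.14), the death ligand Fasl by 1.31 (SE 0.16) and Zbtb16, the transcription factor PLZF, by 1.36 (SE 0.23). Of 10 neutrophil markers 5 rose, among them Camp by 2.49 (SE 0.50), Ngp by 2.43 (SE 0.45), Ltf by 2.35 (SE 0.52) and Mpo by 1.81 (SE 0.35). Of 29 tested cell cycle genes 10 rose, such as the mitotic motor Kif11 by 1.27 (SE 0.21) and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, by 1.25 (SE 0.21), and the list shifted up at camera's preset correlation (adjusted p = 1.46e-15) but not with an estimated correlation (adjusted p = 0.442).

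The remaining genes of the rule fall into the same directions. Chil3 rose by 2.55 and Lcn2, an iron-scavenging protein of neutrophil granules, by 2.40. Also up were C1qb, a complement component of macrophages, by 2.47, Ifitm6 by 2.21 and Itgb2l by 1.92. Falls below Foxp3 were those of Ncmap (-1.85), Sfn (-1.34), Rell1 (-1.32), Aqp9 (-1.29) and Gpc1 (-1.25). Of the 10 largest rises Asns is the 1 that is not a marker or product of myeloid cells as far as these genes are known. For C1qb, Fasl and Tnfrsf9 another probe set showed less than 50% of the change, 0.40, -0.63 and -0.23, and further dim sets stood at 1.498 for C1qb and -0.14 for Tnfrsf9.

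Markers of some other cell types moved with the Foxp3-cre group. Of 10 neutrophil markers 5 rose, with a median change of 1.35, and the marker mean was 9.36 ± 0.50 against 8.01 ± 0.51 in wild type and 8.33 ± 0.46 in CD4-cre (SD, n = 3 arrays). The abundant neutrophil genes S100a8 and S100a9 stood at 0.84 and 1.16, and the receptors Cxcr2 and Csf3r at 0.05 and -0.33, without passing. The monocyte and macrophage mean was 7.32 ± 0.71 against 6.40 ± 0.29, and of 9 markers tested C1qb alone rose. The plasma cell list did not move together: Prg2, which also encodes the major basic protein of eosinophils, rose by 1.42, while Jchain stood at -0.60, Derl3 at -0.05 and Igha at 0.69 without passing. B cell means were 8.03 and 8.21 on Foxp3-cre replicates 2 and 3 and 6.86 on replicate 1, against 6.88 to 7.43 in wild type, and 0 of 7 tested markers passed in limma. T cell markers were level, at 10.50 in wild type, 10.47 in CD4-cre and 10.47 in Foxp3-cre. Signals of other cells were not absent in wild type, where Ighm read 13.71, Jchain 11.90 and Lyz1 10.91 on average, while Ebf1 read 4.16. The B cell list was mixed: in CD4-cre and Foxp3-cre Ighm stood at -0.38 and -0.50, and Ms4a1 at 0.77 and 1.06. Level T cell markers therefore do not show that the samples were free of other cells.

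**Figure D2:**
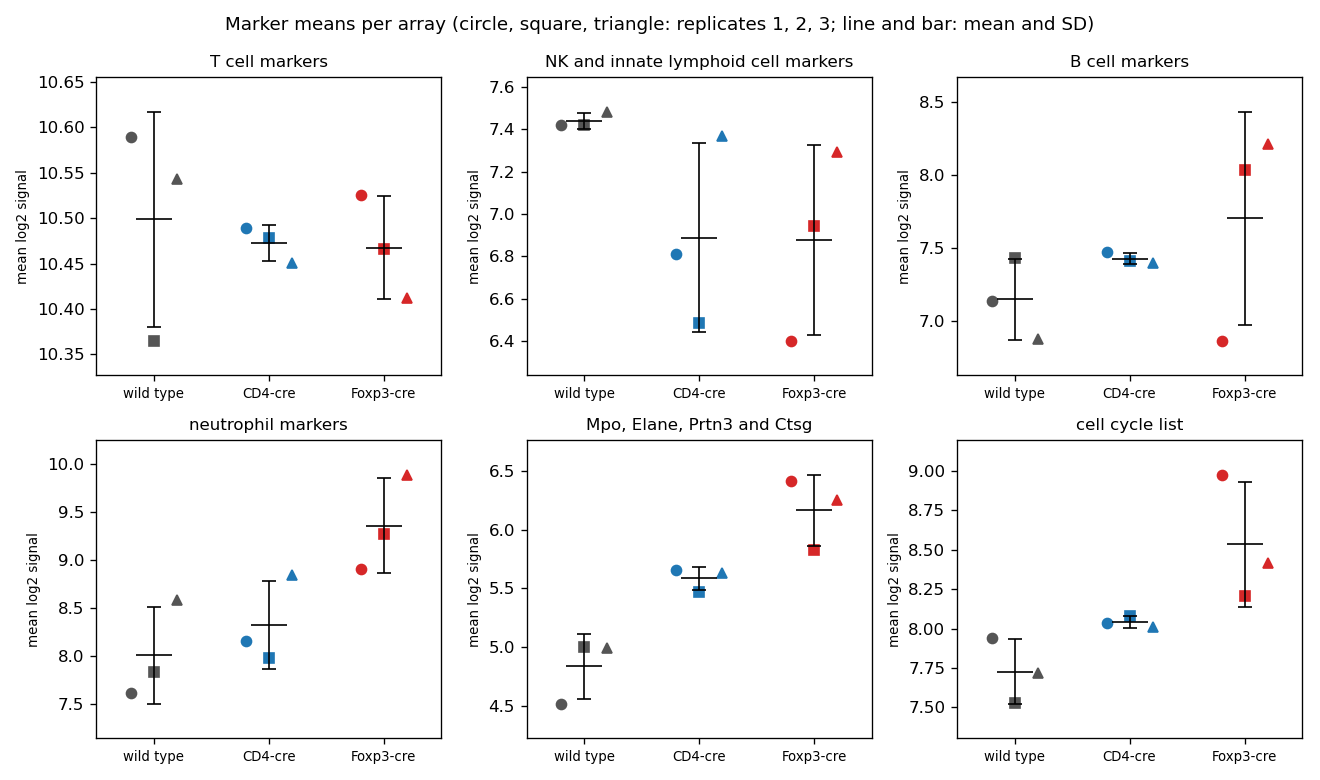
Mean log2 signal of marker genes (vertical axes) on each array, by group, with the mean and SD of 3 arrays per group. The T cell mean is level across groups, while the neutrophil mean of the Foxp3-cre arrays, 8.91, 9.27 and 9.89, lies above that of the 3 wild type arrays, and the cell cycle mean is highest on Foxp3-cre replicate 1, at 8.98.

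By list, cell cycle genes showed the widest shift in Foxp3-cre, with 28 of 29 members higher and a median of 0.83. Of them 10 rose over all genes tested and 25 adjusted over the list alone, including the cyclin Ccnb2 by 1.21 and the spindle protein Nusap1 by 1.23. Camera gave adjusted p = 1.46e-15, and adjusted p = 0.442 with an estimated correlation, and the median was 0.77 without wild type replicate 2. Granulocyte precursor genes, a list of Mpo, Elane, Prtn3 and Ctsg written after the data were seen, rose in 4 of 4 with a median of 1.23, and in CD4-cre all 4 lay higher, by a median of 0.65, with 0 changed in limma. Mpo and Elane also belong to the neutrophil markers, so the lists overlap. On Foxp3-cre replicates 1, 2 and 3 the cell cycle mean was 8.98, 8.21 and 8.42, the precursor mean 6.42, 5.83 and 6.25, and the neutrophil mean 8.91, 9.27 and 9.89. Precursor and cell cycle means thus had the same order within Foxp3-cre, whereas in wild type replicate 1 was highest in cell cycle genes, 7.94, and lowest in precursor genes, 4.51, and in CD4-cre replicate 2 was highest in the first, 8.08, and lowest in the second, 5.47. Effector cytokines shifted down by a median of -0.24 (camera adjusted p = 0.00436, adjusted p = 0.442 with an estimated correlation), where 3 of 7 fell on either adjustment, Ifng, Il4 and Csf2, the last by 0.52. The added NK cell and innate-like T cell genes lay lower in 17 of 18 by a median of -0.31, with 0 fallen and Gzmk risen (camera adjusted p = 6.35e-05, adjusted p = 0.162 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation, shifted down by a median of -0.25 (camera adjusted p = 0.00225, adjusted p = 0.530 with an estimated correlation). Of 18, the stress phosphatase subunit Ppp1r15a fell by 0.71 and Klf6 by 0.46, and 7 fell adjusted over the list alone. NF-kB targets shifted by -0.11 (camera adjusted p = 0.00686, adjusted p = 0.442 with an estimated correlation), with 1 of 23, the signalling adaptor Traf1, down by 0.62, and 7 down adjusted over the list alone. Oxidative phosphorylation genes shifted up by 0.16, with 24 of 29 higher and 0 changed by limma on either adjustment (camera adjusted p = 0.00470, adjusted p = 0.543 with an estimated correlation), Ndufv2 being the highest at 0.37 and Sdhd next at 0.36. Wild type replicate 2 was the lowest array for both, with Ndufv2 at 9.66 against 10.21 and 10.04 and Sdhd at 8.41 against 9.26 and 8.89 on the other wild type arrays, and without it the median of the list was 0.097. Conventional and naive T cell genes shifted by -0.10 (camera adjusted p = 0.0297, adjusted p = 0.543 with an estimated correlation), and Ccr9 fell by 1.03, the 1 of 16 on either adjustment.

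The other lists did not shift in Foxp3-cre by camera, though some members changed. By fry, heat shock genes and chaperones shifted down (adjusted p = 0.0440). The Treg signature had a median of 0.12, a mean of -0.12 and an upward direction in camera (adjusted p = 0.664), with Foxp3 and Tnfrsf9 (-0.54) down and the cytokine subunit gene Ebi3 up by 0.58, and 2 rising and 2 falling adjusted over the list alone. Of 24 activation and homing genes 3 rose, Ahr (the aryl hydrocarbon receptor) by 0.90, the integrin Itgb1 by 0.83 and Myb by 0.62, and Tbx21 fell, with 7 rising and 1 falling adjusted over the list alone (median -0.02, mean 0.10, camera up at adjusted p = 0.172). Hdac1 rose by 0.39 among 12 acetylation and deacetylation enzymes, with 2 rising adjusted over the list alone (camera adjusted p = 0.229). Klf4 fell by 0.57 as 1 of 17 FOXO targets, with 2 adjusted over the list alone (median -0.10, camera adjusted p = 0.0526). None of 19 p53 targets changed on either adjustment by limma (median -0.11, camera adjusted p = 0.0543), with Plk2 at -0.41 and Bbc3 at -0.37. In glycolysis Pdk1, a kinase that restrains pyruvate oxidation, fell by 0.59 as 1 of 16, with 1 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.668). Fatty acid oxidation had 0 of 16 changed by limma on either adjustment (median 0.04, camera adjusted p = 0.758), with Etfdh at 0.46 and Etfa at 0.38. Both were lowest on wild type replicate 2, with Etfdh at 5.99 against 7.29 and 7.19 on the other wild type arrays and 7.28 on average in Foxp3-cre, and Etfa at 8.58 against 9.21 and 8.99. Of 13 heat shock genes and chaperones Dnajb1 fell by 0.99 and Hspb1 by 0.65, with 4 falling adjusted over the list alone (camera adjusted p = 0.221). Oasl1 fell by 0.78 among 22 interferon response genes, the same 1 over the list alone, with a median of -0.14 (camera adjusted p = 0.0533). Rps6 fell by 0.65, the 1 of 21 ribosomal protein genes on either adjustment (camera adjusted p = 0.229).

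Foxp3-cre had 250 changed genes, 126 up and 124 down, 61 of them by over 2-fold. There were 1581 at an unadjusted p under 0.05, against 371.8 by chance, and 1739 with fully separated arrays, 23.4%, against 10% by chance. The count was 567 without wild type replicate 2, 437 and 79 without wild type replicates 1 and 3, 91, 100 and 134 without CD4-cre replicates 1, 2 and 3, and 162 and 71 without Foxp3-cre replicates 2 and 3, and 48 of the 250 passed in all 9 such fits. With only the wild type and Foxp3-cre arrays in the fit 16 genes passed, all among the 250, and 1539 passed with array weights. With the mean neutrophil marker level as a covariate, chosen after the data were seen, 6 genes passed, 1 up and 5 down, of which 3 are among the 250. Many folds kept their size while their standard errors grew, since the covariate follows the groups: Ifng was -1.12 (SE 0.16), Il4 -1.19 (SE 0.18), Cxcr6 -1.31 (SE 0.24), Fasl -1.67 (SE 0.24) and Kif11 1.72 (SE 0.33). Others shrank, such as Chil3 to 0.59 (SE 0.22), Lcn2 to 0.52 (SE 0.24) and Ncmap to -0.71 (SE 0.46). Camp, at 0.47, and Ltf, at 0.18, are part of the covariate, so their loss follows from its construction. Of the 43 genes named and called, 41 passed without wild type replicate 2, all but Ifitm6 and Ltf. In all 9 fits without 1 array 17 of the 43 passed, and 3 passed with the neutrophil covariate. Among the large rises, Ngp and Chil3 passed in 6 of the 9 fits, Lcn2 and Itgb2l in 4, Camp, Mpo and C1qb in 3, and Ltf and Ifitm6 in 2.

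**Figure D3:**
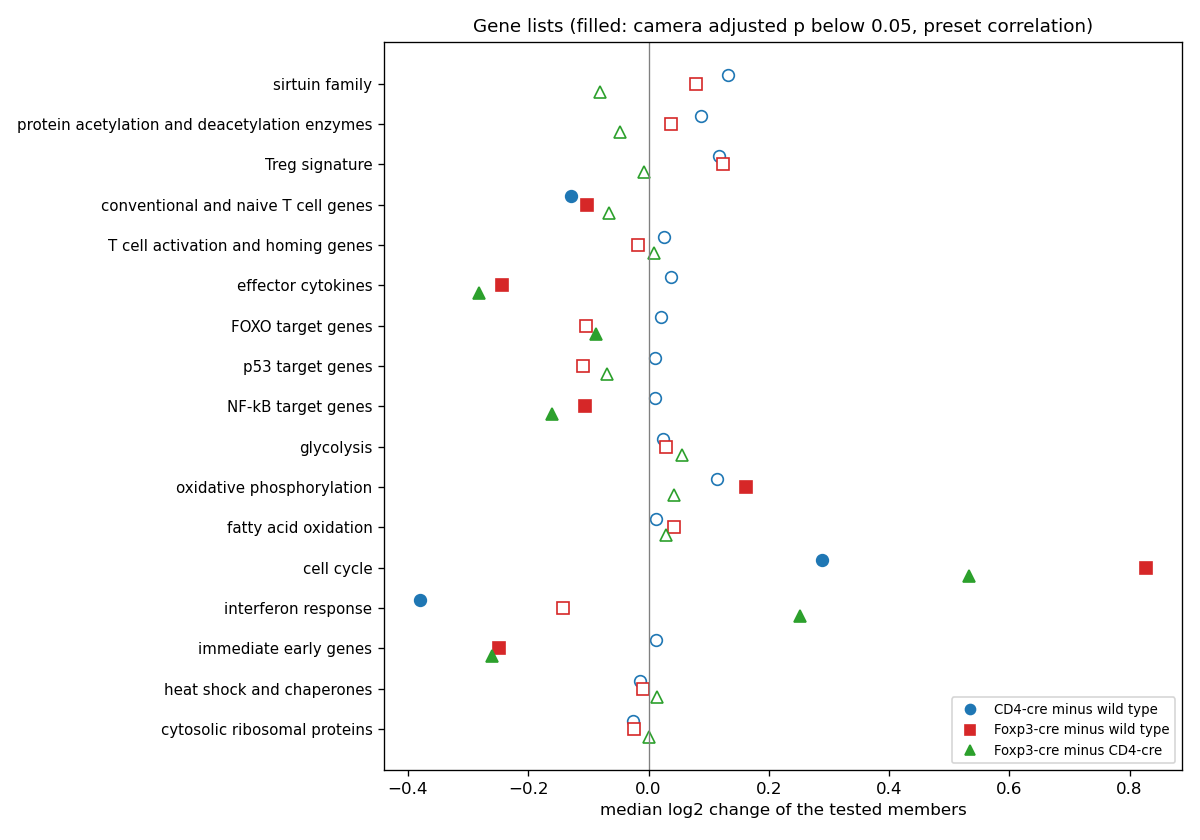
Median log2 change (horizontal axis) of the tested members of each of the 17 gene lists (vertical axis) in 3 contrasts, with filled symbols for camera adjusted p below 0.05 at the preset correlation. The cell cycle list lies farthest to the right, at 0.83 in Foxp3-cre minus wild type, and the interferon response list farthest to the left, at -0.38 in CD4-cre minus wild type.

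Between the knockouts, Foxp3 was the single gene that changed, lower in Foxp3-cre, in the fit without a replicate block. More genes passed with the replicate number as a block, as given below with the processing. The next genes by p, none past the threshold, were higher in Foxp3-cre for Myo6 (1.38, SE 0.21), the decoy receptor Il1r2 (1.18, SE 0.17), Ahr (0.91, SE 0.14), Itgb1 (0.81, SE 0.12) and the peptidase Scpep1 (0.50, SE 0.07), all at limma adjusted p = 0.0805. Lower in Foxp3-cre were Ier5l at -0.74 (adjusted p = 0.0760), Pdk1 at -0.71 (adjusted p = 0.0805), Rab4a at -0.70 and Gpr146 at -0.55 (both adjusted p = 0.128).

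Several lists shifted between the knockouts without a changed member. Cell cycle genes lay higher in Foxp3-cre in 29 of 29 members, by a median of 0.53 (camera adjusted p = 4.63e-15, adjusted p = 0.278 with an estimated correlation), with Kif11 at 0.81 and Bub1 at 0.77 and 12 rising adjusted over the list alone. Interferon response genes were higher in 20 of 22, by a median of 0.25 (camera adjusted p = 1.29e-07, adjusted p = 0.278 with an estimated correlation), with Oasl2 at 0.90, Rsad2 at 0.82 and 2 rising adjusted over the list alone. Immediate early genes were lower by a median of -0.26 (camera adjusted p = 4.43e-05, adjusted p = 0.278 with an estimated correlation), Fosb at -0.75 and Nr4a1 at -0.64, with 2 falling over the list alone. NF-kB targets were lower by -0.16 (camera adjusted p = 4.43e-05, adjusted p = 0.256 with an estimated correlation), Ier3 at -0.43 and Traf2 at -0.36, with 2 falling over the list alone. Effector cytokines were lower by -0.28 (camera adjusted p = 0.00115, adjusted p = 0.278 with an estimated correlation), Il4 at -0.37 and Csf2 at -0.36, with 4 of 7 falling over the list alone. FOXO targets were lower by -0.09 (camera adjusted p = 0.0196, adjusted p = 0.537 with an estimated correlation), Txnip at -0.63 and Klf4 at -0.60, with 2 falling over the list alone. The neutrophil markers, with a median difference of 1.12 between the knockouts, and the monocyte markers, with 1.15, lay on the same side as the cell cycle genes, though 0 of them passed in limma.

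There were 840 genes at an unadjusted p under 0.05 between the knockouts, against 371.8 by chance, and 2207 with fully separated arrays, 29.7%, against 10% by chance. Without wild type replicate 2 72 genes passed, 2 passed without Foxp3-cre replicate 2, and 55 passed when the 6 knockout arrays were fitted alone.

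Averaged over both knockouts, wild type differed in 168 genes, 74 up and 94 down in the knockouts, 19 of them by over 2-fold. The 6 knockout arrays all lay on 1 side of the 3 wild type arrays for 161 of the 168. Asns rose by 2.80 (SE 0.13, limma adjusted p = 2.40e-05), Mpo by 1.48, the phosphatase-related Mtmr9 by 1.30, Cap1 by 1.22 (SE 0.10) and 2610005L07Rik by 1.12, although a second probe set of the last stood at -0.13. 2610005L07Rik stood at 0.74 without wild type replicate 2, and passed in 3 of the 9 fits without 1 array. Ncmap fell by 1.58, Sfn by 1.31, Gpc1 by 1.27, Aqp9 by 1.15 and Rell1 by 1.12. Il4 fell by 1.10 (SE 0.09), Ifng by 0.98 (SE 0.08) and Tbx21 by 0.94 (SE 0.12), and the integrin Itgae, also called CD103, rose by 0.76 (SE 0.15).

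Lists in this contrast repeat parts of the others, since it averages them. Cell cycle genes shifted up by 0.51, with 4 of 29 changed, Ube2c by 0.90, Kif11 by 0.87, Nusap1 by 0.86 and Stmn1 by 0.72, and 22 adjusted over the list alone (camera adjusted p = 2.59e-11, adjusted p = 0.478 with an estimated correlation). With them, all 4 granulocyte precursor genes rose, by a median of 0.93. Of 10 neutrophil markers, with a median of 0.84, 2 rose, and these were Mpo and Elane, which belong to both lists. Interferon response genes shifted down by -0.31, with 1 of 22 changed (Oasl1, -0.83) and 9 adjusted over the list alone (camera adjusted p = 5.48e-06, adjusted p = 0.478 with an estimated correlation). Conventional and naive T cell genes shifted by -0.19, where Ccr9 fell by 0.89, the 1 of 16 on either adjustment (camera adjusted p = 0.00787, adjusted p = 0.478 with an estimated correlation). Effector cytokines shifted by -0.10, with 2 of 7 falling and 3 adjusted over the list alone (camera adjusted p = 0.0131, adjusted p = 0.478 with an estimated correlation). Immediate early genes shifted by -0.11, with Klf6 down by 0.39 and 2 falling over the list alone (camera adjusted p = 0.0406, adjusted p = 0.478 with an estimated correlation). Oxidative phosphorylation genes shifted by 0.13, with 0 of 29 changed by limma on either adjustment (camera adjusted p = 0.00787, adjusted p = 0.478 with an estimated correlation). There were 1497 genes at an unadjusted p under 0.05, against 371.8 by chance. The count of 168 was 399 without wild type replicate 2, 54 without wild type replicate 3, 56, 58 and 67 without CD4-cre replicates 1, 2 and 3, 85 and 87 without Foxp3-cre replicates 2 and 3, and 84 with the neutrophil marker level as a covariate. Of the 168 genes 43 passed in all 9 fits without 1 array, and of the 31 named and called 14 did. Without wild type replicate 2, 25 of the 31 passed, and Itgae, Mtmr9, Ncmap, Kif11, Nusap1 and Ube2c did not. The median of the oxidative phosphorylation genes was then 0.090.

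Of the genes changed against wild type, 35 changed the same way in both knockouts, 10 up and 25 down, and 0 in opposite ways. Asns, Cap1, Ifng, Il4, Ccr9, Gpc1, Sfn and Aqp9 are among them. Independent lists of these sizes would share 0.288 genes up and 0.534 down. Unchanged groups simulated against shared simulated wild type arrays shared 4.5 on average and 17 at most. Genes were drawn independently there, so those values leave out genes that vary together and arrays that stand apart. Across genes, which are not independent replicates, the log2 changes of the knockouts correlated at r = 0.641, below the 0.755 of simulated unchanged groups, while their covariance was 0.0440 against a simulated 0.0218. The 3 wild type arrays were not split between the contrasts, since 1 part would hold a single array, so the share of the overlap that comes from the shared controls is not known. The shared count was 132 without wild type replicate 2, 18 without wild type replicate 3, 10, 4 and 16 without CD4-cre replicates 1, 2 and 3, and 20 and 19 without Foxp3-cre replicates 2 and 3. Of the 250 genes of Foxp3-cre, 243 had the same sign in CD4-cre and 227 were larger in Foxp3-cre, while of the 49 genes of CD4-cre 49 had the same sign in Foxp3-cre and 17 were larger there, so each selection favours the knockout it was made in. Over all genes tested the sign was the same for 76.1%, against 77.5% in simulated unchanged groups.

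**Figure D4:**
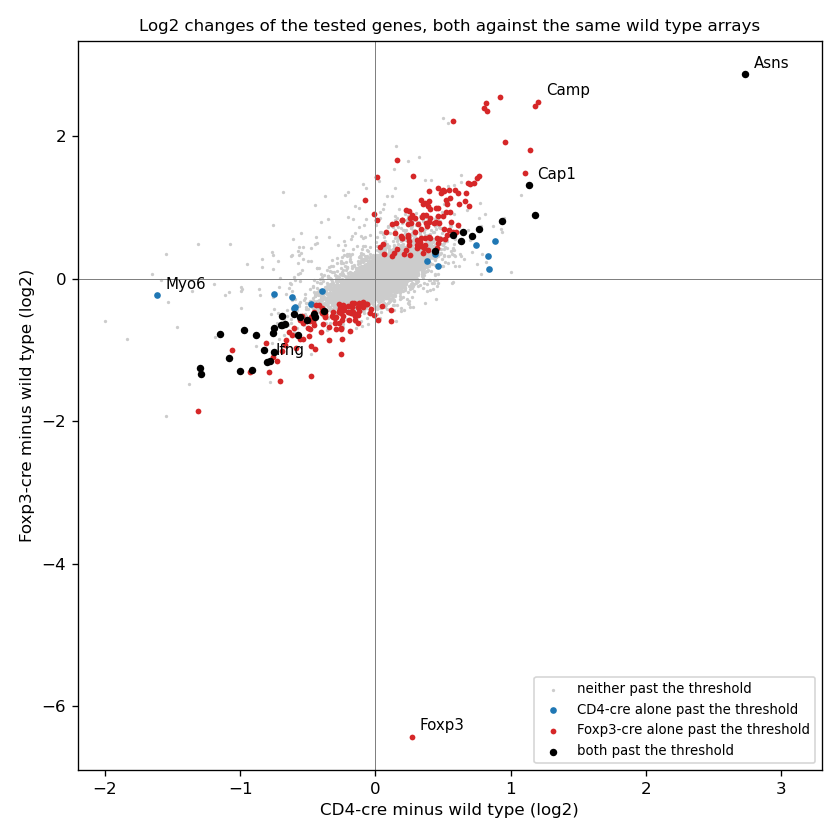
Log2 change of each of the 7436 tested genes in CD4-cre (horizontal axis) and Foxp3-cre (vertical axis), both minus the same 3 wild type arrays, coloured by which contrast passed the threshold. Asns lies at 2.73 and 2.87, and Foxp3 at 0.27 and -6.44.

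Markers of the other cell types showed 0 changed genes by limma in all 4 contrasts. NK and innate lymphoid cell markers had a median of -0.42 in CD4-cre and -0.19 in Foxp3-cre, with Klra8, an NK cell receptor, at -1.55 and -1.92. Medians in CD4-cre and Foxp3-cre were 0.08 and 0.37 for CD8 T cells, 0.04 and 0.12 for dendritic cells, -0.03 and -0.08 for mast cells and basophils, and 0.21 and -0.03 for thymocytes. They were -0.04 and 0.08 for erythroid cells, -0.08 and -0.13 for platelets, 0.03 and -0.02 for stroma and endothelium, and -0.06 and 0.00 for sex-linked genes, lists in which 1 to 3 members were bright enough to be tested.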

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

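The tests of the cell cycle and Foxp3 patterns in this part were chosen after the result was seen, except the counts over other splits of the arrays, which were planned.

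What stood out first was Foxp3, whose change against wild type differed between the knockouts by -6.70 in a test of the difference itself. A loss of regulatory T cells from the Foxp3-cre samples would lower the other signature genes too, but the median difference of the other 28 tested members was 0.015, which argues against it. The limit is that cells were selected by CD25, so Il2ra, and members that go with CD25 in other T cells, could stay level regardless. A Cre insertion that parts the probed sequence from the Foxp3 transcript could give the same picture with the cells intact. Foxp3 has 1 probe set here, so no second set can show whether another part of the transcript is still present, and this stays open. A real loss of Foxp3 transcript in cells that keep their other signature genes stays open as well. Loss of Sirt1 alone as its cause is argued against, if Sirt1 is lost in CD4-cre as labelled. There Foxp3 read 9.68, 9.69 and 9.62, against 9.16, 9.68 and 9.34 in wild type.

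Several lists also differed between the knockouts by camera at its preset correlation, with medians of 0.53 for cell cycle genes, 0.25 for interferon response genes, -0.26 for immediate early genes, -0.16 for NF-kB targets, -0.28 for effector cytokines and -0.087 for FOXO targets. None of these passed with an estimated correlation, where the lowest adjusted p was 0.256.

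The cell cycle genes were weighed as a pattern, being higher in the Foxp3-cre arrays than in wild type by a mean of 0.81 (95% interval 0.29 to 1.32). RNA quality of wild type replicate 2 is argued against as the whole cause, since the median without that array was 0.77. Carry-over of dividing granulocyte precursors might contribute: with the mean of Mpo, Elane, Prtn3 and Ctsg as a covariate the shift was 0.42 (95% interval -1.25 to 2.08), too wide to tell because that mean follows the groups, and with the neutrophil marker mean instead it was 1.11 (95% interval 0.18 to 2.03). All 4 of those genes rose in Foxp3-cre, by a median of 1.23, and their mean had the order of the cell cycle mean within Foxp3-cre but not within wild type or CD4-cre, 1 of 3 groups, so carry-over stays open. More division of the regulatory T cells themselves, the biological explanation, was not tested.

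Probe sets that do not carry exactly 1 gene name were not used in the comparisons, and they held signal as well. Of 1022 such sets tested with limma, 8 changed in CD4-cre, 33 in Foxp3-cre, 3 between the knockouts and 21 with both knockouts averaged.

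Counts from other splits of the arrays were set beside the real counts. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The changed genes numbered 49 for CD4-cre against wild type and at most 0 in another split (1 of 10 as large, the real one), 250 for Foxp3-cre against at most 1 (1 of 10), and 1 between the knockouts against at most 0 (1 of 10). For shifted lists the values were 3 and at most 3 (4 of 10), 6 and at most 6 (2 of 10), and 6 and at most 6 (3 of 10). For both knockouts averaged, 100 of the 840 splits were drawn. The real one gave 168 genes and the highest other 61, so 1 of 100 was as large. Splits that mix wild type with knockout arrays put the group differences into the spread, which keeps their counts low. The samples may also not be independent, so the draw cannot exclude chance for that count. The 61 came from 1 of the 3 drawn splits, the real one included, that keep the real wild type arrays together, and with other wild types the highest was 6. For its 6 shifted lists the highest other split gave 8 and 20 of 100 gave as many, so chance is not excluded there either.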

How the results depend on the processing

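The covariates for the neutrophil marker mean and for the beta-actin 5' minus 3' signal were chosen after the data were seen, the other settings before. Given in the order CD4-cre, Foxp3-cre, between the knockouts and averaged, the changed genes of 49, 250, 1 and 168 became 1298, 1539, 812 and 1604 with array weights (0.0824 for wild type replicate 2), 22, 16, 55 and 91 in fits of only the groups compared, 113, 631, 9 and 446 at adjusted p below 0.10, and 196, 550, 32 and 446 with the beta-actin covariate. The neutrophil covariate gave 84, 6, 1 and 84. CD4-cre had 29 with a filter at the 60th percentile. Between the knockouts, quantile normalization gave 5, median centring 8 and the replicate number as a block 96. The block rests on the numbers alone. Residuals of 7 of 9 pairs with the same number correlated above 0.1, with a median of 0.20, against -0.10 for the 18 other pairs. Residuals from a group mean sum to 0 over its arrays. Positive values of same-number pairs thus push the others below 0, and the -0.10 is no separate baseline. Of the 9 arrays, 7 correlated best with an array of their own number. Whether equal numbers mark a shared preparation is not given in the labels. Leaving out 1 array gave 4 to 191, 71 to 567, 1 to 72 and 54 to 399 genes, and 4 to 132 instead of 35 shared ones. The lowest came without CD4-cre replicate 2, Foxp3-cre replicate 3 and wild type replicate 3, and the highest without wild type replicate 2. Shifted lists in CD4-cre went from 3 to 5 without a filter on dim genes, with the mean of all probe sets, and at adjusted p below 0.10. With an estimated correlation 0 lists passed in all 4 contrasts, and with fry 0, 4, 2 and 1. In Foxp3-cre fry passed effector cytokines (adjusted p = 0.0138), cell cycle genes, NF-kB targets and heat shock genes and chaperones (each adjusted p = 0.0440). Between the knockouts it passed the Treg signature with Foxp3 in it (adjusted p = 0.0258) and NF-kB targets (adjusted p = 0.0463). With both knockouts averaged it passed effector cytokines (adjusted p = 0.0441). Averaged, the 6 lists became 3 to 8 on leaving out 1 array, with 3 without wild type replicate 1 or 3. The change of Sirt1 in Foxp3-cre, 0.03, turned to -0.35 with array weights (adjusted p = 0.0380) and ranged from -0.35 to 0.22 over the arrays left out. Averaged it turned to -0.29 with array weights (adjusted p = 0.0389), and the range was -0.32 to 0.25. Of 2666 values of named genes under other settings, 2185 counted as kept, 476 no longer passed, 1 newly passed and 4 reversed with a call in either fit. Kept means the same side of the threshold, and a change of sign counted as kept where neither fit passed. Of the list calls 414 were kept and 66 no longer passed. Fewer arrays or other groups in the spread estimate come with the settings that use them, and otherwise the cause was not tested. Signals near the array background, such as Foxp3 in Foxp3-cre, limit the folds.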

Other observations

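All tests in this part were chosen after the result was seen.

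Changed genes lay close together on chromosome 4, by the gene order of GRCm38.p6. With both knockouts averaged, 9 of 100 neighbouring tested genes had changed where 2.26 would by even spread: Cap1, Hdac1, Smpdl3b, Sytl1, Wdtc1 and Stmn1 rose, and Ndufs5, Sfn and Ncmap fell. Shuffled positions gave a stretch as dense in a share of 0.0118 for CD4-cre, 0.0137 for Foxp3-cre and 0.125 averaged. Stretches, neighbouring pairs and whole chromosomes were looked at in 3 contrasts that share arrays, 9 forms in all. On the whole of chromosome 4, 11 genes changed in CD4-cre where 3.07 would by even spread, 29 against 15.7 in Foxp3-cre and 21 against 10.5 averaged. Adjusted over the 9 forms, the shares for the whole chromosome were 0.0072, 0.0308 and 0.0434, those for stretches 0.0308, 0.0308 and 0.141, and those for pairs 0.272, 0.0522 and 0.0522.

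Random positions of the changed genes stay open, with shares of 0.0072 to 0.272, because the forms were picked after the data were seen and shuffling treats genes as independent. A strain segment that came along with the floxed Sirt1 gene is argued against for the stretch on chromosome 4 by position alone, since Sirt1 lies on chromosome 10. Of the 40 tested genes beside Sirt1 1 changed, Prf1, where 0.904 would by chance (exact hypergeometric test, p = 0.600). That count covers the surroundings of Sirt1 and says nothing on chromosome 4. Neighbouring genes switched together would share a direction, and 33.3% of the 9 went the less common way. By even spread 2.26 changed genes would lie there anyway, in either direction, so the directions cannot decide this. A strain segment on chromosome 4 itself, which might give such a stretch, was not tested.

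A candidate explanation for the rise of Asns is an ATF4 response, the amino acid stress programme that Asns belongs to. With both knockouts averaged, 20 other listed ATF4 targets had a median of -0.085, 14 of them lower (limma camera adjusted p = 0.0557 over the 3 lists added, 0.116 with an estimated correlation), and 0 changed in limma. In CD4-cre 15 of the 20 were lower, by a median of -0.097 (limma camera adjusted p = 0.0408, adjusted p = 0.118 with an estimated correlation), and in Foxp3-cre 12, by -0.12 (adjusted p = 0.126, adjusted p = 0.162 with an estimated correlation). Averaged, Psat1 stood at 0.32, Ddit3 at -0.30 and Trib3 at -0.11. An ATF4 response would raise these genes, so the result was negative.

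Fewer NK cells or innate-like T cells in the knockout samples might lie behind the falls of Ifng, Il4 and Xcl1. With both knockouts averaged, 17 of 18 listed genes of such cells were lower, with a median of -0.37 (limma camera adjusted p = 5.77e-06 over the 3 lists added, adjusted p = 0.116 with an estimated correlation). Klra8 stood at -1.74 and Ccl5 at -0.68, without passing, and Gzmk rose by 1.01. The mean of the NK and innate lymphoid cell markers was 6.40 to 7.37 on the 6 knockout arrays, below the 7.42 to 7.48 of the wild type arrays. Separation by CD4 and CD25 should remove most NK cells, but Klra8 still read 6.92 and Gzma 10.09 on average in wild type. Several of these genes are also expressed by activated T cells, so the explanation stays open. Xcl1 fell by 0.97 and was named after its values were seen.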
